A study of Mus musculus with 14 samples.

How the data were processed

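Liver RNA from C57BL/6J mice made obese by diet had been measured in 14 samples on a 1-colour Affymetrix mouse expression array, with 1 array per sample. Whether each sample came from a separate mouse is not stated. Per the labels, 5 samples came from liver treated with vehicle, 4 from liver treated with an adenovirus carrying a short hairpin RNA (shRNA) against green fluorescent protein (GFP), and 5 from liver treated with an adenovirus carrying an shRNA against Jnk1, the protein kinase encoded by Mapk8. An shRNA is a small folded RNA that the cell processes into a guide which lowers the matching messenger RNA. Replicate numbers were taken from the labels, which number the GFP group 1, 2, 3 and 5. Per the labels' protocols, total RNA was extracted from pulverized liver with a column kit and labelled with biotin.

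The deposited values were linear probe set intensities for 22690 probe sets on 14 arrays. The software behind these intensities, its detection calls and any background correction are not given in the sources used here. All deposited intensities lay above 0, and the largest was 8401. The mean of each array after removal of 2% of the probe sets at either end lay between 150.05 and 150.06, so the deposited arrays had been scaled to a common trimmed mean. Array medians still ranged from 41.8 to 58.3, a span of 0.48 on the log2 scale.

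Before the data were examined it was fixed that arrays would be quantile normalized if their medians spanned more than 0.2 on the log2 scale, and this applied. After quantile normalization, intensities under the 5th percentile (2.01) were set to it and values were log2 transformed. The 64 Affymetrix control probe sets were left out of the tests, and so were the 40% of the other 22626 probe sets with the lowest mean, which left 13575 probe sets. The lowest mean among them corresponded to an intensity of 28.4. Without detection calls there was no direct bound on background, so a fold against a group whose mean lay under this intensity is uncertain in size. The number of arrays limits the precision.

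Gene symbols came from the platform annotation of 2016. Of all probe sets, 20393 had 1 symbol, 691 had several and 1606 had none, and probe sets with several symbols were given no gene name. Entrez gene identifiers of 20364 probe sets matched the mouse RefSeq gene table of assembly GRCm38.p6, and no symbol needed a change. The kept probe sets covered 8027 genes. Each gene was represented by its kept probe set of highest mean over all arrays, and 2871 genes had more than 1 kept probe set. No genome positions were used.

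Differences were tested with limma 3.58.1 in R 4.3.3, with 3 group means fitted to all 14 arrays at once, so that the groups shared 1 estimate of the spread (11 residual degrees of freedom and 4.94 from the prior). Variances were moderated with an intensity trend, and p-values were adjusted over the 13575 probe sets by the Benjamini-Hochberg method. A probe set was called changed at an adjusted p under 0.05. Fold changes are differences of mean log2 intensity, given with their standard error (SE), and group values are means with the standard deviation (SD). Mapk8 and the array quality measures were also compared by exact two-sided permutation tests.

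The 31 gene lists, with 816 entries, were written from textbook knowledge before the data were examined, and include markers of the other cell types that liver holds. Of the entries, 726 were on the array and 626 were kept. Each list was tested against all other genes with camera, limma's competitive gene set test, at its preset correlation between genes of 0.01, with adjustment over the lists. The same test with an estimated correlation was the alternative.

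The named genes of each comparison followed a rule set before the data were examined. It took Mapk8, Mapk9 and Mapk10, the 10 genes that rose most and the 10 that fell most among called genes whose groups did not overlap, and up to 4 members with the smallest p from each list, more where a list passed. It also took a focal set of lipid and glucose genes whatever their result. Clones and predicted genes were counted without description.

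Other normalizations, filters, a pseudocount of 16 in place of the floor, variance models, array weights, 2-group fits, 1 probe set per gene, the replicate number as a block and leaving out each array in turn were tried as alternatives. Overlaps between comparisons with shared arrays were set beside 20 simulations of unchanged groups and 20 splits of the shared arrays. The fit was tested on simulated data in which 200 of 13575 probe sets changed. For Jnk1 against GFP shRNA, 38.8% of simulated changes of 0.5 on the log2 scale, 76.1% of those of 1 and 98.5% of those of 2 were recovered, with 7 false calls. In simulated lists, the 3 lists shifted by 0.4 were called and 0 of 21 unshifted lists were. Simulated noise was independent between genes, so this does not test the preset correlation of camera.

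The 18 probe sets of the bacterial and phage spike-in transcripts, which are added to the hybridization in fixed amounts, were averaged on the log2 scale of the deposited intensities to give a spike-in level per array. No 2 arrays were duplicates: at most 2 probe sets had an identical deposited value in a pair of arrays, and the highest correlation of 2 arrays was 0.984.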

Results

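The data comprised 14 liver expression arrays in 3 groups: vehicle (n = 5), GFP shRNA adenovirus (n = 4) and Jnk1 shRNA adenovirus (n = 5). The labels describe a liver-specific knockdown of Jnk1 in mice with diet-induced obesity. The GFP virus was taken as the control for infection and for hairpin expression, and vehicle as the control without virus. The labels do not say whether the 2 viruses were given at the same dose, and off-target effects of the Jnk1 hairpin were not tested, so a difference between the viruses is not shown to come from the loss of Jnk1. The labels number the samples as replicates without saying that each came from a separate mouse, and p-values measure the spread between these samples. Array 2 of the GFP group stood apart, with a median intensity of 58.3 against 45.8 to 47.8 in the other 3 and a mean correlation of 0.942 with its own group. The spike-in level of the Jnk1 arrays was lower and more variable, at 8.36 ± 0.32 (SD, n = 5, log2) against 8.91 ± 0.08 (n = 4) with GFP shRNA and 8.91 ± 0.10 (n = 5) with vehicle. This difference passed an exact permutation test against the GFP group (p = 0.0159) and against vehicle (p = 0.00794). The ratio of 3' to 5' signal for Gapdh, a sign of RNA integrity, was 0.735 ± 0.021 (SD) with Jnk1 shRNA and 0.686 ± 0.020 with GFP shRNA (exact permutation p = 0.0159). The same ratio for actin was 1.10 and 1.09 (exact permutation p = 0.548). The signal from the 5' end of 18S ribosomal RNA ranged from 52.0 to 1976 on the Jnk1 arrays and from 851 to 1567 on the others.

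The targeted gene was examined first. Mapk8 fell in the Jnk1 shRNA group to 40.2% of its level with GFP shRNA, from a log2 intensity of 7.38 ± 0.09 (SD, n = 4) to 6.07 ± 0.18 (n = 5). The log2 fold change was -1.31 ± 0.11 (SE, adjusted p = 3.5e-07 in limma), and the groups did not overlap (exact permutation p = 0.00794, the smallest that 126 splits can give). Against vehicle it fell by 1.40 on the log2 scale, while GFP shRNA and vehicle did not differ in the test (-0.08 ± 0.11, adjusted p = 0.769). These values are from the Mapk8 probe set with the highest mean. A second Mapk8 probe set fell by 1.12 ± 0.22 against GFP shRNA. The third gave -0.12 ± 0.14 against GFP shRNA (adjusted p = 0.561) and fell by 0.51 ± 0.14 against vehicle (adjusted p = 0.00696), so the probe sets disagreed on the size of the loss. Which part of the transcript each probe set reads was not analysed here. Mapk9, which encodes the related kinase JNK2, gave 0.08 ± 0.15 against GFP shRNA (adjusted p = 0.734). Against vehicle Mapk9 rose by 0.41 ± 0.14 (adjusted p = 0.034) on 1 of its 3 probe sets, and this call was lost when any 1 of 5 arrays was left out (adjusted p up to 0.0932), with folds of 0.29 to 0.51 over all arrays left out. Mapk10, the third member of the family, lay below the filter on both of its probe sets.

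**Figure D1:**
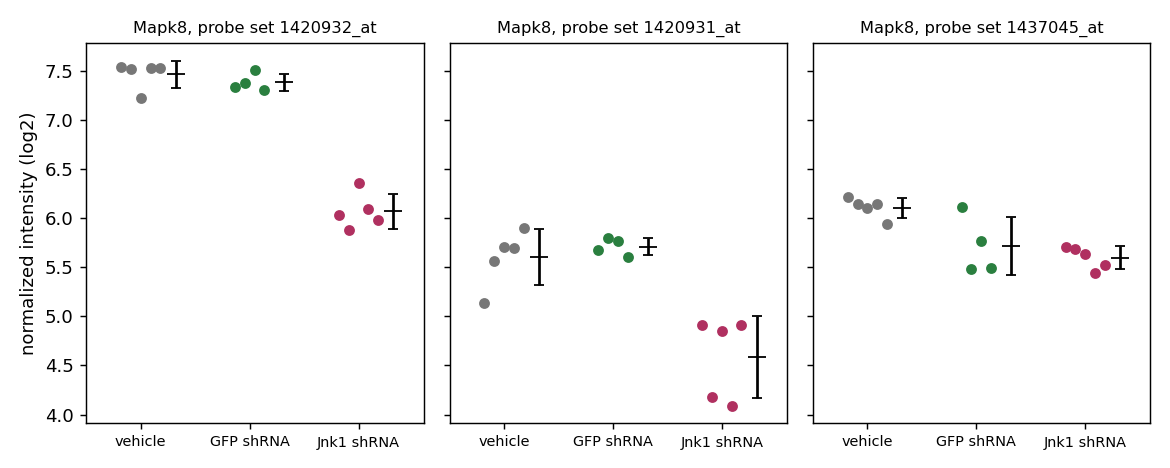
Normalized log2 intensity of the 3 Mapk8 probe sets on each array (points), by group, with the group mean and SD beside the points (n = 5 vehicle, 4 GFP shRNA, 5 Jnk1 shRNA). On the probe set with the highest mean the Jnk1 shRNA arrays lie between 5.88 and 6.36 and the GFP shRNA arrays between 7.31 and 7.51, whereas on the third, which fell against vehicle alone, the GFP and Jnk1 shRNA groups overlap.

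Livers with Jnk1 shRNA differed from livers with GFP shRNA in genes of mitochondrial energy metabolism, which were higher, and in genes of antigen presentation, of macrophages and of cholesterol synthesis, which were lower. These list shifts passed at the preset correlation of camera, and none passed with an estimated correlation (adjusted p from 0.272 to 0.697). Afp, the fetal serum protein alpha-fetoprotein, rose 59.7-fold (log2 fold change 5.90 ± 0.28, SE, adjusted p = 1.44e-09, n = 5 and 4). Igfbp2, which encodes an insulin-like growth factor binding protein, fell 8.10-fold (-3.02 ± 0.28, adjusted p = 8.63e-07). Ppargc1b, a coactivator of mitochondrial and lipid genes, rose 2.84-fold (1.51 ± 0.35, adjusted p = 0.00324), and Mttp, which loads lipid onto very-low-density lipoprotein, rose 1.79-fold (0.84 ± 0.08, adjusted p = 7.72e-07). With the spike-in level as a covariate, an alternative added after seeing the data, Ppargc1b gave 1.42 and lost its call (adjusted p = 0.104). Against vehicle Ppargc1b did not pass, at 0.34 with Jnk1 shRNA and -1.16 with GFP shRNA. Its difference between the viruses thus lay more in a low level with GFP shRNA than in a rise over vehicle. In all, 4497 of 13575 probe sets (33.1%) changed, 2350 upward and 2147 downward, and 658 of them by at least 2-fold. They represented 2741 of 8027 genes, and the 2 groups did not overlap in 3818 of all 13575 probe sets (28.1%), where chance gives 1.59%.

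The other genes that rose most were Smcp (4.16 ± 0.47), Krt23, a keratin (3.79 ± 0.42), Kcnk1, a potassium channel (3.53 ± 0.51), Cyp2b9, a cytochrome P450 (3.45 ± 0.37), and Defb1, a defensin (3.28 ± 0.16). They were followed by Tarbp2 (3.05 ± 0.52), which encodes a partner of Dicer in small RNA processing, Csad, an enzyme of taurine synthesis (2.71 ± 0.20), Metrn (2.61 ± 0.56) and Pdk4, a kinase that inhibits pyruvate dehydrogenase (2.55 ± 0.28). With GFP shRNA the mean of Afp, Smcp, Krt23, Tarbp2 and Metrn lay under an intensity of 28.4, so the size of these folds is uncertain, and so is that of Prm1 and Per3 below, whose means with Jnk1 shRNA lay under it. The genes that fell most after Igfbp2 were Prodh, which degrades proline (-2.54 ± 0.17), BC023105 (-2.50 ± 0.41), Masp1, a protease of the lectin complement pathway (-2.21 ± 0.11), and Slc46a3 (-2.18 ± 0.11). Alas2, the erythroid enzyme of heme synthesis, fell by 2.02 ± 0.14, as did Hsd3b5, a steroid dehydrogenase (-2.01 ± 0.35), and Prm1, a protamine (-1.95 ± 0.32). The remaining 2 of the 10 were clones.

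Within the focal set, Srebf1, a transcription factor of lipid synthesis, fell by 0.48 ± 0.16 (adjusted p = 0.0283), and G6pc, the last enzyme of glucose output, rose by 0.77 ± 0.24 (adjusted p = 0.0192). Both calls rested on single arrays. Without GFP shRNA array 1 Srebf1 gave -0.36 and without Jnk1 shRNA array 3 -0.40 (adjusted p = 0.102 and 0.0757), and without GFP shRNA array 2 or 5 G6pc gave 0.59 or 0.62 (adjusted p = 0.0722 and 0.0709). Srebf1 also lost its call when arrays were scaled to the same median (-0.25, adjusted p = 0.27) and with the spike-in level as a covariate (-0.41, adjusted p = 0.299). The other members did not pass: Ppargc1a gave 0.27 ± 0.14, Fasn 0.33 ± 0.28, Scd1 0.29 ± 0.24, Apoc3 0.05 ± 0.04, Apob -0.21 ± 0.17, Pck1 -0.17 ± 0.12, Irs2 -0.09 ± 0.32 and Igfbp1 -0.07 ± 0.08. As deposited, Igfbp1 passed (-0.35, adjusted p = 0.0224) and so did Apoc3 in the other direction (-0.28, adjusted p = 0.0345).

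**Figure D2:**
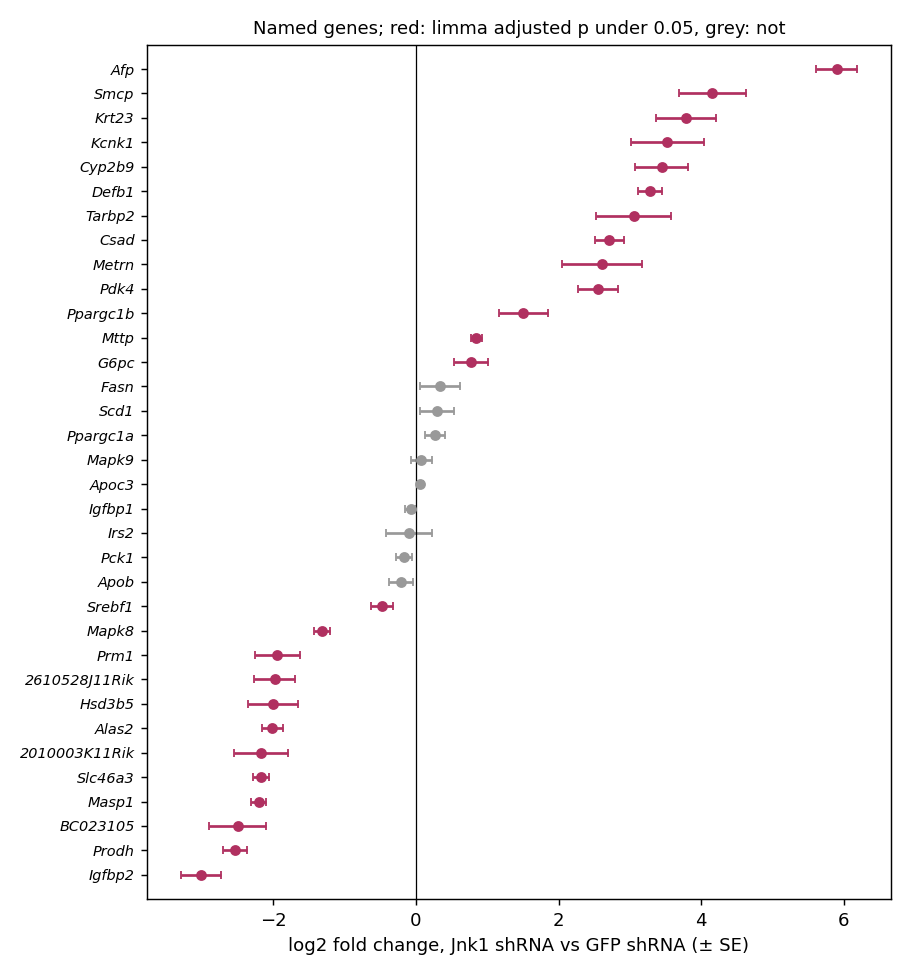
Log2 fold change of Jnk1 shRNA (n = 5) against GFP shRNA (n = 4) for Mapk8 and Mapk9, the 10 genes with the largest rise, the 10 with the largest fall and the focal set. Bars are SE; red points have a limma adjusted p under 0.05. Afp is farthest to the right at 5.90 and Igfbp2 farthest to the left at -3.02, and 8 of the 12 focal genes are grey.

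Of the 31 lists, 10 shifted at the preset correlation and 0 with an estimated correlation. Of 64 measured oxidative phosphorylation genes, 47 rose and 0 fell (49 and 1 when adjusted over the list alone), with a median log2 fold change of 0.34 (adjusted p = 3.25e-12, and 0.272 with an estimated correlation). Ndufs7 and Ndufa8 of complex I rose by 0.79 ± 0.08 and 0.68 ± 0.08, Cox6b1 of complex IV by 0.59 ± 0.07 and Atp5o of the ATP synthase by 0.48 ± 0.06. Of 23 TCA cycle genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.38, adjusted p = 3.86e-04, and 0.272 with an estimated correlation). Cs, citrate synthase, rose by 1.07 ± 0.08, Dlst by 0.66 ± 0.07 and Mdh2 by 0.63 ± 0.08, while Aco1, the cytosolic aconitase, fell by 0.58 ± 0.06. Of 31 genes of fatty acid oxidation and ketogenesis, 16 rose and 6 fell (16 and 6 adjusted over the list alone; median 0.28, adjusted p = 0.00335, and 0.488 with an estimated correlation). Crat, which exchanges acetyl groups with carnitine, rose by 1.77 ± 0.16, and Hadhb and Hadha of the mitochondrial trifunctional protein by 1.00 ± 0.07 and 0.86 ± 0.10. The spike-in level differed by -0.55 (log2) between these groups. Within the Jnk1 group, the array with the highest spike-in level, array 2 (8.76), had a mean oxidative phosphorylation level 0.09 above vehicle, and the other 4 lay 0.19 to 0.34 above. The TCA cycle level did not follow the spike-in level in this way, at 0.33 on array 2 and 0.20 on array 1, the array with the lowest spike-in level.

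**Figure D3:**
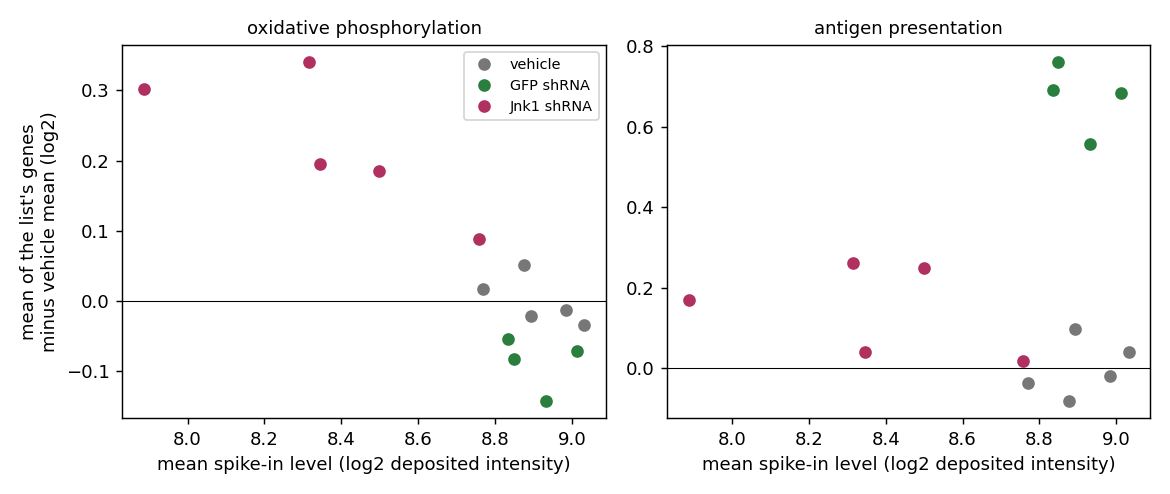
Mean log2 level of the measured oxidative phosphorylation genes (left) and antigen presentation genes (right) on each array, less the vehicle mean, against the mean spike-in level (log2 deposited intensity). Each point is an array. The Jnk1 shRNA arrays have the higher oxidative phosphorylation levels and spike-in levels of 7.89 to 8.76, all below the lowest control array (8.77), and array 2 of that group, the rightmost of its points, lies nearest the controls on the left plot.

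The lists that shifted downward were mostly of immune and other non-hepatocyte cells. Of 15 antigen presentation genes, 9 fell and 1 rose (the same adjusted over the list alone; median -0.57, or -0.36 with arrays scaled to the same median; adjusted p = 0.00439, and 0.286 with an estimated correlation). H2-Aa, H2-Eb1 and Cd74, of the MHC class II pathway, fell by 1.71 ± 0.17, 1.25 ± 0.15 and 1.24 ± 0.16, and Psme1, a proteasome activator subunit, rose by 0.62 ± 0.10. Of 22 macrophage and Kupffer cell markers, 12 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.46, adjusted p = 5.50e-04, and 0.437 with an estimated correlation). Mpeg1 fell by 1.30 ± 0.16, Cd5l by 0.82 ± 0.11, Adgre1 by 0.77 ± 0.13 and Mrc1 by 0.57 ± 0.09. Of 17 stellate cell and fibrosis markers, 5 fell (4 adjusted over the list alone; median -0.33, or -0.16 with arrays scaled to the same median; adjusted p = 0.0304, and 0.272 with an estimated correlation), among them Reln (-0.95 ± 0.09) and Dcn (-0.45 ± 0.07). Of 13 endothelial markers, 5 fell (5 adjusted over the list alone; adjusted p = 0.0422, and 0.437 with an estimated correlation), among them Stab2 (-0.65 ± 0.09) and Clec4g (-0.56 ± 0.09). The erythroid list passed on Alas2, its 1 measured gene (adjusted p = 0.0422, and 0.272 with an estimated correlation). Of 22 mature hepatocyte genes, 10 fell and 1 rose (the same adjusted over the list alone; median -0.14, or -0.34 as deposited; adjusted p = 0.0421, and 0.372 with an estimated correlation), including the transcription factor Hnf4a (-0.52 ± 0.07) and the tyrosine catabolic enzymes Hgd (-0.33 ± 0.06) and Hpd (-0.26 ± 0.04). Of 19 cholesterol synthesis genes, 7 fell and 0 rose (the same adjusted over the list alone; median -0.23, or -0.08 with arrays scaled to the same median; adjusted p = 0.0455, and 0.697 with an estimated correlation), including Stard4 (-0.92 ± 0.16), Cyp51 (-0.73 ± 0.15) and Ebp (-0.48 ± 0.07). When arrays were scaled to the same median, Dcn, Clec4g, Hnf4a, Hgd, Hpd and Ebp lost their calls at -0.25, -0.34, -0.36, -0.22, -0.34 and -0.32 (adjusted p from 0.0666 to 0.226). Cyp51 gave -0.31 and Hgd -0.22 with the spike-in level as a covariate, and neither passed (adjusted p = 0.331 and 0.105).

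Of 10 T and NK cell markers, 0 passed the limma test (0 adjusted over the list alone), and the list did not pass (adjusted p = 0.804). Of 33 interferon-stimulated genes, 5 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.808): Rsad2 and Lgals3bp rose by 1.93 ± 0.34 and 1.25 ± 0.14, and the interferon-inducible GTPases Ifi47 and Iigp1 fell by 1.46 ± 0.19 and 0.58 ± 0.09. Of 15 circadian clock genes, 3 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.458). Dbp, Per3 and Nr1d2 fell by 2.03 ± 0.38, 1.13 ± 0.19 and 1.00 ± 0.10, and Cry1 rose by 1.19 ± 0.26. Under median scaling the count of changed probe sets was 4130, of which 72.3% were higher, against 52.3% of the 4497, and the median of all probe sets moved to 0.09. With the spike-in level as a covariate the count was 2172, and with array 2 alone for the Jnk1 group, which assumes that the lone sample varied like the others, it was 1330; both alternatives were added after seeing the data.

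**Figure D4:**
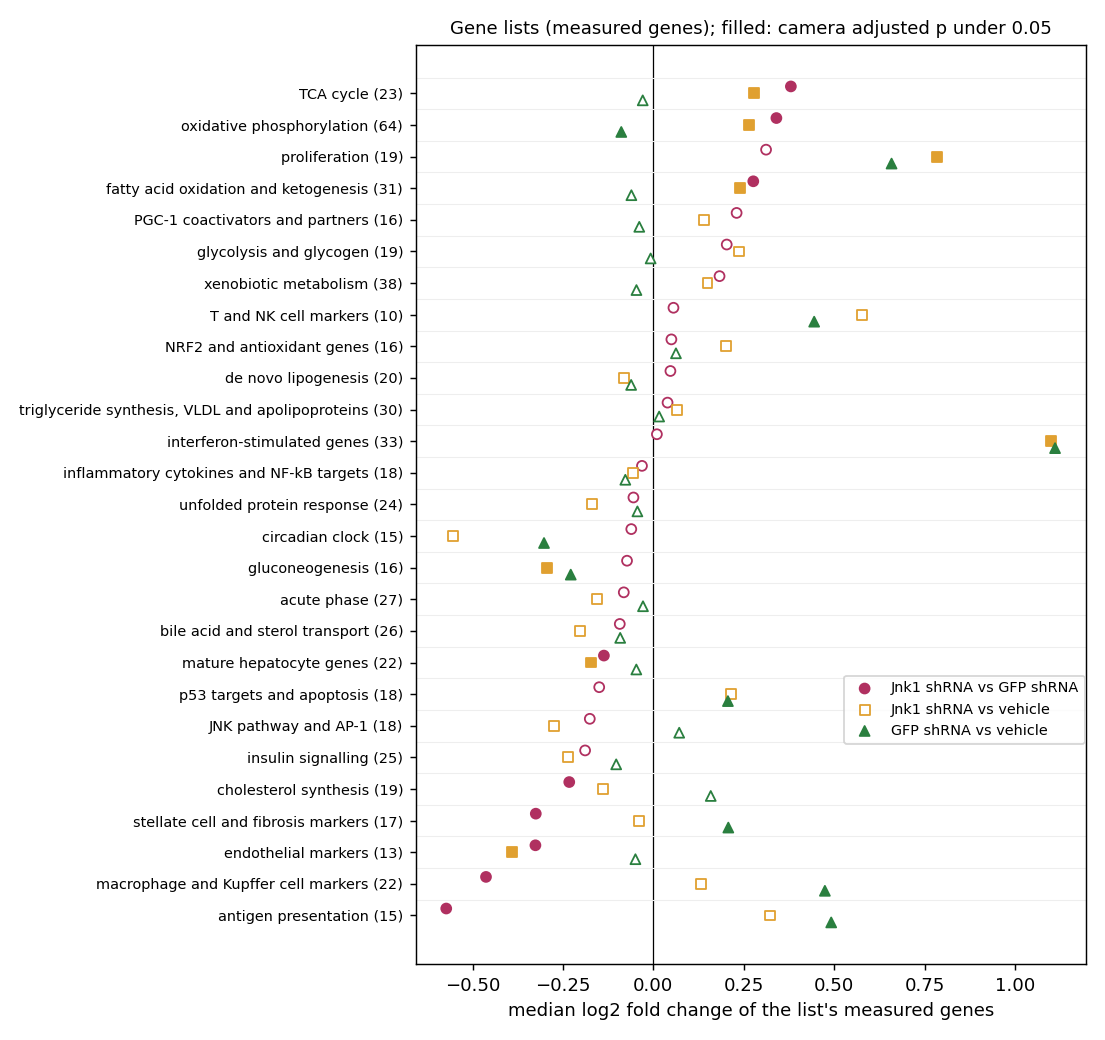
Median log2 fold change of each gene list with at least 10 measured genes (number in brackets) in the 3 comparisons. Filled symbols have a camera adjusted p under 0.05 at the preset correlation. In Jnk1 shRNA against GFP shRNA (circles) the TCA cycle (0.38) and oxidative phosphorylation (0.34) lie highest and antigen presentation lowest (-0.57); interferon-stimulated genes lie at 1.10 and 1.11 in the 2 comparisons with vehicle.

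Against vehicle, livers with Jnk1 shRNA had higher interferon-stimulated, proliferation and mitochondrial genes and lower genes of gluconeogenesis, endothelium and mature hepatocytes. These list shifts passed at the preset correlation of camera, and proliferation alone passed with an estimated correlation too (adjusted p = 0.0129, and 0.296 to 0.575 for the others). Afp rose 96.6-fold (log2 fold change 6.59 ± 0.27, SE) and Kcnk1 by 6.32 ± 0.48 on the log2 scale, both from a vehicle mean under an intensity of 28.4. The antiviral gene Rsad2 rose 13.7-fold (3.78 ± 0.32, adjusted p = 1.7e-07), and Vsig4, a receptor of Kupffer cells, fell 8.23-fold (-3.04 ± 0.17, adjusted p = 3.18e-09). In all, 5099 probe sets changed (37.6%), 2563 upward and 2536 downward, and 806 by at least 2-fold; they represented 3095 genes.

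The other large rises were Smcp (4.76 ± 0.44), Mcm6, a DNA replication helicase subunit (3.93 ± 0.39), Slfn4 (3.90 ± 0.33), Cyp2b9 (3.61 ± 0.35), Defb1 (3.61 ± 0.16), Csad (3.47 ± 0.19) and Slc22a29 (3.42 ± 0.23); the vehicle means of Smcp, Mcm6 and Slfn4 lay under an intensity of 28.4. Igfbp2 (-3.18 ± 0.26), the clock output gene Dbp (-2.85 ± 0.35), Prodh (-2.83 ± 0.16) and Masp1 (-2.74 ± 0.10) fell, and so did the Kupffer cell lectin Clec4f (-2.40 ± 0.13), Slc46a3 (-2.40 ± 0.11), Hsd3b5 (-2.26 ± 0.33) and Ugt2b38 (-2.22 ± 0.45). Of the focal genes, Mttp rose by 0.78 ± 0.07, and Srebf1 and Pck1, the rate-controlling enzyme of gluconeogenesis, fell by 0.68 ± 0.15 and 0.53 ± 0.11 (adjusted p = 0.00172 and 0.00139). Ppargc1b gave 0.34 ± 0.33 (adjusted p = 0.439), Ppargc1a -0.33 ± 0.13, G6pc 0.38 ± 0.22, Fasn 0.12 ± 0.26, Scd1 -0.08 ± 0.22, Apoc3 0.05 ± 0.04, Apob -0.18 ± 0.16, Irs2 -0.54 ± 0.31 and Igfbp1 -0.18 ± 0.08, none past the threshold. Ppargc1a passed without vehicle array 1 or 3 or GFP shRNA array 1 (as far as -0.41, adjusted p down to 0.0278), Irs2 without vehicle array 1 (-0.79, adjusted p = 0.037), and Igfbp1 without vehicle array 2 or Jnk1 shRNA array 2 (as far as -0.23, adjusted p down to 0.0188), as deposited (-0.49, adjusted p = 0.00125) or scaled to the same median (-0.46, adjusted p = 0.0157). Apoc3 turned to -0.32 as deposited (adjusted p = 0.0115) and gave -0.29 scaled to the same median (adjusted p = 0.12).

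In this comparison 8 lists shifted. Of 33 interferon-stimulated genes 25 rose (28 adjusted over the list alone; median 1.10, adjusted p = 4.52e-12, and 0.296 with an estimated correlation), including Gbp3 (2.14 ± 0.18), Lgals3bp (1.96 ± 0.13) and Bst2 (1.42 ± 0.11). Of 19 proliferation genes 12 rose (14 adjusted over the list alone; median 0.79, adjusted p = 7.78e-06, and 0.0129 with an estimated correlation), including Cdk1 (2.47 ± 0.26, from a vehicle mean under an intensity of 28.4), Rrm1 (1.26 ± 0.10) and Stmn1 (0.75 ± 0.10). Of 64 oxidative phosphorylation genes 39 rose and 3 fell (40 and 3 adjusted over the list alone; adjusted p = 5.50e-07, and 0.334 with an estimated correlation), with a median of 0.26, or 0.14 as deposited and 0.17 with arrays scaled to the same median. Of 23 TCA cycle genes 15 rose and 2 fell (16 and 4 adjusted over the list alone; median 0.28, adjusted p = 0.00181, and 0.321 with an estimated correlation). Of 31 genes of fatty acid oxidation 18 rose and 7 fell (18 and 9 adjusted over the list alone; median 0.24, adjusted p = 0.0215, and 0.575 with an estimated correlation). The spike-in level differed by -0.55 between these groups too. Ndufa8 rose by 0.73 ± 0.07, Cs by 1.14 ± 0.08 and Hadhb by 1.12 ± 0.07. Of 16 gluconeogenesis genes 8 fell and 1 rose (the same adjusted over the list alone; median -0.29, adjusted p = 0.0201, and 0.342 with an estimated correlation), including the glucagon receptor Gcgr (-1.39 ± 0.09), Tat (-1.10 ± 0.17) and Gpt (-0.71 ± 0.07). Of 13 endothelial markers 8 fell (the same adjusted over the list alone; adjusted p = 0.00657, and 0.334 with an estimated correlation), including Stab2 (-0.81 ± 0.09) and Ptprb (-0.71 ± 0.13). Of 22 mature hepatocyte genes 12 fell (13 adjusted over the list alone, with 1 that rose; median -0.17, or -0.42 as deposited and -0.39 with arrays scaled to the same median; adjusted p = 0.00897, and 0.296 with an estimated correlation), including Hnf4a (-0.58 ± 0.07) and Hgd (-0.47 ± 0.06). With the spike-in level as a covariate, Pck1 lost its call (-0.29, adjusted p = 0.263) and so did Srebf1 (-0.61, adjusted p = 0.0941) and Ugt2b38 (-1.97, adjusted p = 0.0807), and 2858 probe sets changed.

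The GFP virus alone was set against vehicle to show what infection and a control hairpin changed. Genes induced by interferon were among those that rose most: Gbp2, a guanylate-binding protein, rose 7.21-fold (log2 fold change 2.85 ± 0.40, SE, n = 4 and 5), Igtp 6.44-fold (2.69 ± 0.20, adjusted p = 1.03e-06), Gbp6 6.26-fold (2.65 ± 0.23) and Zbp1, a sensor of foreign nucleic acid, 5.27-fold (2.40 ± 0.20). The Kupffer cell markers Vsig4 and Clec4f fell 4.17-fold (-2.06 ± 0.18) and 3.96-fold (-1.98 ± 0.14). In all, 350 probe sets changed (2.58%), 278 upward and 72 downward, 123 by at least 2-fold, representing 225 genes. Without GFP shRNA array 5 the count was 198, and in the fit of these 2 groups alone it was 209.

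BC023105 (3.16 ± 0.41), Kcnk1 (2.79 ± 0.51), Mcm6 (2.69 ± 0.41), Ms4a4b (2.67 ± 0.50), Slfn4 (2.58 ± 0.35) and Gbp3 (2.35 ± 0.19) completed the 10 largest rises, and the vehicle means of Kcnk1, Mcm6, Ms4a4b, Slfn4 and Zbp1 lay under an intensity of 28.4. In the fit of 2 groups, which leaves the folds as they are and estimates the spread anew, Kcnk1, Ms4a4b and Col3a1 (below) did not pass (adjusted p = 0.0547, 0.0644 and 0.0577). The immediate-early gene Nr4a1 fell by 1.13 ± 0.22, Slc25a25, a mitochondrial carrier, by 1.11 ± 0.22, Tob1 by 0.92 ± 0.11 and the chemokine Cxcl12 by 0.67 ± 0.13. The other 4 of the largest falls, Gtf2ird1 (-1.46), Vangl2 (-1.20), N4bp2l1 (-0.87) and Cnmd (-0.77), did not pass without any 1 of 9, 10, 5 and 3 arrays, with adjusted p up to 0.102, 0.105, 0.124 and 0.0644. Over the 14 arrays left out in turn, Gtf2ird1 ranged from -1.72 to -0.99, Vangl2 from -1.37 to -1.04, N4bp2l1 from -0.95 to -0.77 and Cnmd from -0.84 to -0.69. Of the focal genes Ppargc1a fell by 0.60 ± 0.14 (adjusted p = 0.0343), a call lost without any 1 of 6 arrays (adjusted p up to 0.125), with folds of -0.71 to -0.52 over all arrays left out. Ppargc1b gave -1.16 ± 0.35 (adjusted p = 0.099), Srebf1 -0.20 ± 0.16, Fasn -0.21 ± 0.28, Scd1 -0.38 ± 0.24, Mttp -0.07 ± 0.08, Apob 0.03 ± 0.17, Pck1 -0.36 ± 0.12, G6pc -0.39 ± 0.24, Irs2 -0.45 ± 0.32 and Igfbp1 -0.11 ± 0.08, and Apoc3 differed by less than its SE of 0.04.

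In this comparison 10 lists shifted, and 4 of them kept their calls with an estimated correlation. Of 33 interferon-stimulated genes 25 rose (30 adjusted over the list alone; median 1.11, adjusted p = 1.89e-40, and 0.018 with an estimated correlation). Of 15 antigen presentation genes 7 rose (12 adjusted over the list alone; median 0.49, adjusted p = 9.09e-16, and 0.0039 with an estimated correlation), led by the immunoproteasome subunits Psmb9 (1.80 ± 0.17), Psmb10 (1.31 ± 0.10) and Psmb8 (1.11 ± 0.15) and the peptide transporter Tap1 (1.53 ± 0.13). Psmb9, Psmb8 and Tap1 are also members of the interferon-stimulated list, so the shifts of these lists are not independent results. Of 19 proliferation genes 11 rose (15 adjusted over the list alone; median 0.66, adjusted p = 3.42e-13, and 3.11e-04 with an estimated correlation), including Cdk1 (1.73 ± 0.28, from a vehicle mean under an intensity of 28.4). Of 17 stellate cell and fibrosis markers 2 rose, Vim (0.98 ± 0.19) and Col3a1 (0.64 ± 0.13) (5 adjusted over the list alone; median 0.21, or 0.13 with arrays scaled to the same median; adjusted p = 0.00155, and 0.032 with an estimated correlation). Of 22 macrophage and Kupffer cell markers 8 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.47, adjusted p = 7.61e-09, and 0.193 with an estimated correlation). Mpeg1 and Lgals3 rose by 1.56 ± 0.16 and 1.32 ± 0.11, while the 2 that fell were Vsig4 and Clec4f, which mark resident Kupffer cells.

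The other 5 lists had few called members, and scaling to the same median moved the median of all probe sets to -0.11. Among 10 T and NK cell markers Nkg7 rose (1.93 ± 0.23, from a vehicle mean under an intensity of 28.4; 2 adjusted over the list alone; adjusted p = 8.50e-04, and 0.089 with an estimated correlation). Among 16 gluconeogenesis genes Tat fell by 0.69 ± 0.18 (6 adjusted over the list alone; median -0.23, or -0.41 with arrays scaled to the same median; adjusted p = 8.50e-04, and 0.193 with an estimated correlation). Among 64 oxidative phosphorylation genes Ndufa2 fell by 0.34 ± 0.08 (0 adjusted over the list alone; median -0.09, or -0.14 as deposited and -0.27 with arrays scaled to the same median; adjusted p = 0.00124, and 0.623 with an estimated correlation). The calls of Tat and Ndufa2 were lost without any 1 of 12 and 9 arrays (adjusted p up to 0.167 and 0.116), with folds of -0.87 to -0.56 and -0.39 to -0.30 over all arrays left out. Among 18 p53 targets and apoptosis genes Cdkn1a, a cell cycle inhibitor, rose by 1.08 ± 0.18 (1 adjusted over the list alone; median 0.21, or 0.10 with arrays scaled to the same median; adjusted p = 0.036, and 0.288 with an estimated correlation). Of 15 circadian clock genes 0 passed the limma test, also when adjusted over the list alone, with a median of -0.30 (adjusted p = 0.036, and 0.193 with an estimated correlation). Outside these lists, the lipid droplet gene Cidec and the lipoprotein lipase gene Lpl rose by 1.67 ± 0.30 and 1.04 ± 0.14, Cidec from a vehicle mean under an intensity of 28.4.

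The Jnk1 shRNA group was also compared with both controls at once. The same direction passed against both for 3529 probe sets, 1835 higher and 1694 lower, and 29 passed in opposite directions. They represented 2152 genes, among them Mapk8, Afp, Cyp2b9, Igfbp2, Prodh, Masp1, Mttp, Cs and Hadhb. Both comparisons use the same Jnk1 arrays, so chance values are shared. Unchanged simulated groups gave at most 0 such probe sets. They leave little to call in either comparison, so this count does not measure what the shared arrays add. Independent lists of these sizes would share 444 higher and 401 lower. With the Jnk1 arrays split between the comparisons the count was 2053 to 2478 over 20 splits. Each comparison then keeps fewer Jnk1 arrays, which by itself can lower the count. The covariance of the fold changes was 0.234, against 0.0166 in the simulation. With the spike-in level as a covariate the count was 1833.

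The 2 viruses shared 267 changes against vehicle, 221 higher and 46 lower, which is 76.3% of the 350 probe sets changed by the GFP virus, and 6 went opposite ways. Kcnk1, Mcm6, Slfn4, Gbp3, Cdk1 and Nkg7 rose and Vsig4 and Clec4f fell with both viruses. Unchanged simulated groups shared at most 1, a count that again does not measure what the shared arrays add. Independent lists would share 52.5 higher and 13.5 lower. With the vehicle arrays split the count was 85 to 179, and fewer vehicle arrays per comparison can by itself lower it. Fold changes of the 2 viruses correlated across probe sets at 0.415, below the 0.470 that the shared vehicle arrays gave in the simulation, and had a covariance of 0.0713 against 0.0165. Of the 350 probe sets, 159 also differed between the viruses. With Jnk1 shRNA, 68 of them lay farther from vehicle and 91 lay back toward vehicle or past it. The GFP arrays that selected these probe sets enter the second comparison with the opposite sign, which by itself favours the latter. Without GFP shRNA array 5 the shared count was 161.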

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

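The test of mitochondrial genes against hepatocyte share, the separate tests of oxidative phosphorylation and of the TCA cycle, and both tests of cell types against antigen presentation were chosen after the result was seen. One array lay far from the others of its group, by Dixon's gap over the group's range, in 14 of the 381 gene and group pairs tested, and chance gives about 1 in 20. The ratio was 0.962 for Mapk8 (vehicle 3 lowest, 7.22 against a mean of 7.53), 0.71 for Cyp2b9 (vehicle 4 lowest), 0.83 for Dbp (vehicle 5 highest), 0.746 for Iigp1 (vehicle 1 highest), 0.732 for Btg2 (vehicle 2 lowest) and 0.779 for Ndufa2 (vehicle 2 highest). With GFP shRNA it was 0.962 for Dlst and 0.886 for Gcgr (array 2 lowest), 0.909 for Vim (array 2 highest), 0.88 for H2-Aa (array 3 lowest), and 0.867 for Clec4f and 0.864 for Ugt2b38 (array 1 lowest). With Jnk1 shRNA it was 0.777 for G6pc (array 1 lowest) and 0.734 for H2-Eb1 (array 3 highest). Among quality measures it was 0.837 for the median intensity (GFP shRNA 2 highest, 58.3 against 46.7), 0.889 for the Gapdh ratio (GFP shRNA 5 lowest, 0.656 against 0.696) and 0.874 for the mean correlation with the own group (GFP shRNA 2 lowest, 0.942 against 0.965).

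Other splits of the arrays were counted for each comparison. In Jnk1 against GFP shRNA, 1 of 100 splits, the real one, gave 4497 changed probe sets (highest other 2457), and 2 of 100 gave 10 shifted lists (highest other 10). In Jnk1 shRNA against vehicle, 1 of 100 gave 5099 probe sets (highest other 6), but 19 of 100 gave 8 lists or more (highest other 14). In GFP shRNA against vehicle, 1 of 100 gave 350 probe sets (highest other 226), but 15 of 100 gave 10 lists or more (highest other 12). The real split gave the largest of 100 counts of probe sets in all 3 comparisons, which argues against chance for these counts. For the lists of Jnk1 against GFP shRNA another split gave as many, and 0 lists shifted with an estimated correlation. Chance was therefore argued against less firmly there, and not for the number of lists in either comparison with vehicle. Of 100 regroupings of all arrays, 1, the real one, gave 3529 changes against both controls (highest other 0), and 1 gave 267 changes shared by the viruses (highest other 0). Regroupings mix the groups and leave little to share, so they do not measure what the shared arrays add to these counts.

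Oxidative phosphorylation and TCA cycle genes were higher with Jnk1 shRNA than with GFP shRNA, by a mean of 0.311. The median was 0.29 to 0.46 for oxidative phosphorylation and 0.38 to 0.55 for the TCA cycle under 3 scalings, none of which tests a distortion common to all 3. A larger share of hepatocytes was predicted to raise mature hepatocyte genes, and these differed by -0.206 (95% interval -0.286 to -0.127). Their mean takes in genes such as Hsd3b5 (-2.01), whose level may change within hepatocytes. Markers of macrophages, stellate cells and endothelium were lower too (medians -0.46, -0.33 and -0.33), as a larger share would give. The test therefore does not decide on the share of hepatocytes. With the spike-in level as a covariate the joint difference was 0.226 (0.122 to 0.329), that of TCA cycle genes 0.358 (0.229 to 0.486) against GFP shRNA and 0.333 (0.207 to 0.459) against vehicle, and that of oxidative phosphorylation genes 0.178 (0.0679 to 0.288) against GFP shRNA. For oxidative phosphorylation against vehicle it dropped from 0.223 to 0.0894 (-0.0189 to 0.198), so a difference in hybridization could account for that part. Spike-in levels did not overlap between the Jnk1 arrays and the control arrays, so the adjusted values rest on the slope within groups. The knockdown and a processing difference confined to the Jnk1 arrays, beyond what spike-ins record, stay open, as does the effect of normalization.

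Of the 15 clock genes 5 fell, Dbp, Tef, Per3, Nr1d2 and Nfil3, and 3 rose, Cry1, Arntl and Clock, with Jnk1 shRNA against GFP shRNA. The list as a whole did not shift (camera adjusted p = 0.458), and its median was -0.06, or 0.14 with arrays scaled to the same median. Members that move both ways cancel in a test for a common direction and in a median. These values therefore do not decide whether the clock changed. A different hour of collection was predicted to lower clock output genes of the evening phase like Dbp (-2.03). The 3 measured, chosen after the clock genes were seen, differed by -0.768 (-1.03 to -0.505), a smaller fall than that of Dbp. Wee1 among them did not fall, and camera gave p = 0.0421, and 0.0647 with an estimated correlation. A different hour could thus account for a part of these changes and stays open. The labels give no hour, and an effect of the knockdown or the hairpin on the clock would give the same values. The hybridization difference was not tested for these genes as a group.

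Antigen presentation genes were lower with Jnk1 shRNA than with GFP shRNA, with a mean difference of -0.526. Their median against vehicle was 0.49 with GFP shRNA and 0.32 with Jnk1 shRNA (camera adjusted p = 0.182 for Jnk1 shRNA). For macrophage markers it was 0.47 and 0.13 (adjusted p = 0.764 for Jnk1 shRNA, whose mean was -0.12). The lower values are thus relative to a group in which the medians of both lists lay above vehicle. This does not hold for every member. Against vehicle 3 antigen presentation genes fell with Jnk1 shRNA and 8 rose, and H2-Aa, at -1.24, was among the former. Of the macrophage markers 5 fell and 6 rose, with Vsig4 at -3.04 and Clec4f at -2.40, both of which also fell with GFP shRNA. Fewer T and NK cells were argued against, since their markers differed by 0.114 (-0.180 to 0.408) from GFP shRNA. Fewer B cells were not tested and stay open. Of 3 measured B and plasma cell markers 1 fell against GFP shRNA, with a median of -0.39 (camera adjusted p = 0.174). With the spike-in level as a covariate the difference of antigen presentation genes was -0.584 (-0.802 to -0.366), so it did not shrink. All Jnk1 arrays had lower spike-in levels than all control arrays (at most 8.76 against at least 8.77). The covariate therefore cannot exclude a hybridization difference confined to the Jnk1 arrays. Fewer macrophages than with GFP shRNA could account for the lower antigen presentation genes, since macrophage markers differed by -0.461 (-0.703 to -0.218). A lower expression within these cells stays open and was not tested.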

How the results depend on the processing

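The spike-in covariate, array 2 alone for the Jnk1 group, and leaving out both GFP shRNA 2 and vehicle 1 were chosen after seeing the data. Of 201 gene results, 176 kept their direction and their side of the threshold under each alternative set before the data were examined in which their probe set was tested, leaving out 1 array included. With the lowest 60% left out 171 of the 201 were tested, and Smcp, Metrn and Ms4a4b passed the filter in 9, 8 and 6 of the 14 fits without 1 array. The exceptions included 2 reversals: Apoc3 as deposited gave -0.28 against GFP shRNA and -0.32 against vehicle. With 1 probe set per gene, which tests fewer features, 2790 changed against GFP shRNA, 3128 against vehicle and 2186 against both. With 2 groups per fit GFP shRNA against vehicle gave 209. Camera with an estimated correlation gave 0, 1 and 4 lists in the 3 comparisons. The replicate number as a block gave 6 lists for Jnk1 against GFP shRNA and 4101, 4825 and 247 probe sets. Residuals of the 13 same-number pairs correlated at -0.235 to 0.121, and 5 correlated best with their own number. No chance level was computed for this count, so it does not exclude a weak pairing. The numbers were not taken as pairs in the main fit. The spike-in covariate gave 2172, 2858 and, against both controls, 1833. Array 2 alone for the Jnk1 group, a lone sample assumed to vary like the others, gave 1330, 1906 and 215, 1147 against both controls and 118 shared by the viruses. Without GFP shRNA 2 and vehicle 1 the 3 counts were 4356, 5407 and 283. Leaving out 1 array gave 3841 to 4591, 4575 to 5502 and 198 to 383 probe sets, 3058 to 3512 against both controls and 161 to 299 shared, 7 to 10, 7 to 11 and 8 to 11 lists, and -1.39 to -1.26 for Mapk8. The lowest counts of GFP shRNA against vehicle (198) and of shared changes (161) came without GFP shRNA 5. Of 169 called gene results, 10 lost their call without some array, and 3 of the others gained one. Except where a construction is named, the cause was not tested. Without detection calls, the signal over background limits folds at low intensity.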

Other observations

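The gene lists of sex-dependent, fetal liver and evening clock genes, the gene families and Arntl were chosen after values had been seen, and so were the tests in this part. Of 38 xenobiotic metabolism genes, 17 rose and 7 fell with Jnk1 shRNA against GFP shRNA (18 and 7 adjusted over the list alone), a list that did not pass (adjusted p = 0.0973). The glutathione transferases Gstm3, Gsta4 and Gstm1 rose by 2.51 ± 0.17 (SE), 1.89 ± 0.15 and 1.04 ± 0.10, and Cyp2f2 fell by 1.77 ± 0.09. Of 18 p53 targets and apoptosis genes, 5 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.979): Cdkn1a and Ccng1 rose by 2.32 ± 0.18 and 1.42 ± 0.13, and Trp53inp1 and Btg2 fell by 1.42 ± 0.20 and 1.49 ± 0.33. Of 19 glycolysis and glycogen genes, 6 rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.143), including Pfkl (1.00 ± 0.20), Pgam1 (0.87 ± 0.08) and Gbe1 (0.73 ± 0.13), and Pfkl lost its call with the spike-in level as a covariate (0.47, adjusted p = 0.258), as did Btg2 (-1.48, adjusted p = 0.0744). Of 20 lipogenesis genes, 2 rose, Me1 (1.36 ± 0.23) and Pgd (1.03 ± 0.14), and 5 fell, among them Fads1 (-0.99 ± 0.11) and Elovl6 (-0.67 ± 0.13; the same adjusted over the list alone; adjusted p = 0.872). Of 26 bile acid genes, 4 rose and 9 fell (6 and 9 adjusted over the list alone; adjusted p = 0.447), with Akr1d1 at 1.18 ± 0.07 and Slc27a5 at -0.66 ± 0.07. Of 27 acute phase genes, 3 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.507), with Saa3 at 2.37 ± 0.38.

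In the same comparison the remaining lists did not pass either. Genes that rose and fell numbered 2 and 5 of 16 for gluconeogenesis (3 and 5 adjusted over the list alone), with the glucagon receptor Gcgr at -1.03 ± 0.10, 1 and 7 of 25 for insulin signalling, 9 and 7 of 30 for triglyceride synthesis and lipoproteins (11 and 7 adjusted over the list alone), 3 and 0 of 16 for PGC-1 coactivators and partners, 4 and 5 of 24 for the unfolded protein response and 5 and 2 of 16 for NRF2 and antioxidant genes. They numbered 0 and 4 of 18 for the JNK pathway and AP-1 (0 and 2 adjusted over the list alone), 0 and 2 of 18 for inflammatory cytokines (0 and 0 adjusted over the list alone), 3 and 2 of 19 for proliferation, 0 and 0 of 5 for neutrophil, 0 and 1 of 3 for B cell and 1 and 2 of 3 for cholangiocyte markers. For the lists without such a second pair it was the same. Arntl, which encodes the clock transcription factor BMAL1, rose by 1.09 ± 0.29 against GFP shRNA and by 1.55 ± 0.28 against vehicle. It gave 1.00 against GFP shRNA with the spike-in level as a covariate and did not pass (adjusted p = 0.173). Against vehicle, 8 antigen presentation genes rose and 3 fell (8 and 4 adjusted over the list alone), H2-Aa by 1.24 ± 0.16, while Psme1 rose by 1.11 ± 0.10, and 6 macrophage markers rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.182 and 0.764 for the 2 lists).

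The hypothesis that Jnk1 shRNA shifted sex-dependent liver expression was tested on genes taken as not seen before, 3 female-predominant and 13 male-predominant. At least 1 of the 13 had already entered a fixed list or the named genes, so they were not all new. Of these, 1 and 1 rose and 0 and 7 fell against GFP shRNA. Their mean difference, female less male, was 1.27 (95% interval 0.510 to 2.02), so such a shift may be present, on few female-predominant genes. Over these unseen genes camera gave p = 0.105 for the female-predominant and 0.00125 for the male-predominant ones, and with an estimated correlation neither passed (p = 0.217 and 0.127). The sex of the mice is not given.

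The hypothesis that the rise of Afp belonged to a wider rise of fetal liver and regeneration genes was tested on 6 genes whose values had not been seen. Their mean difference was 0.835 (0.434 to 1.24) and 4 rose, so a shift of the group may be present, though camera over these 6 gave p = 0.00982, and 0.0987 with an estimated correlation. Gene families, formed from the leading letters of symbols, were looked through after values had been seen. Of 47 Mrpl and 27 Mrps genes, which encode mitochondrial ribosomal proteins, 17 and 13 rose and 4 and 1 fell against GFP shRNA, and 10 and 10 rose and 4 and 3 fell against vehicle. Neither family passed over the 89 families (adjusted p = 0.0582 for both against GFP shRNA, and 0.647 and 0.272 against vehicle).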
